A study of Homo sapiens with 4 samples.

How the data were processed

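MicroRNA (miRNA) levels were measured with single-colour Cy5 arrays in MCF-7, an established human breast cancer cell line that responds to oestrogen. Per the labels' protocols, cells were kept in flasks and moved to plates of 6 wells, ethanol was added in volumes of 10 microlitres to fresh medium each 3 days, and control wells received none. Total RNA was extracted, and 2 micrograms were tailed with poly(A), ligated to a tag and stained with Cy5 by a service provider. The series design gives 2 experiments, each with 1 control array and 1 array of cells kept in ethanol at 25 mM over 4 weeks, 4 arrays in all. A label of the ethanol samples writes the dose as 25 nm, which conflicts with the design text, and the millimolar dose is used here. The experiment number in the sample titles was read as pairing a control with an ethanol array.

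The deposited scanner files hold, per the file headers, the median intensity of each spot and its standard deviation, with no background column and no detection call. Scanner, image software and annotation release are not given in the sources used here. The deposited value table holds whole numbers, in intensity units, that the authors background-subtracted and normalized by a method not given in the sources used here. Its log2 values correlated across probes at 0.999 with the levels computed here on each array, and it served as an alternative source.

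Each array carried 3968 spots, of which 3796 belonged to 1898 human miRNA probes and 4 were empty. The mean brightness of the empty spots was 30.8 on control 1, 30.0 on ethanol 1, 28.6 on control 2 and 29.5 on ethanol 2. Because the files have no local background, a probe counted as detected when its mean brightness exceeded the mean of the empty spots by more than 3 times their mean standard deviation. Probes detected on at least 2 of the 4 arrays were tested, which left 589. The number of arrays limits the precision.

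Spot intensities were background-corrected by the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50. Spots of a probe were averaged on the log2 scale, and the arrays were quantile-normalized over the 1898 probes. Ethanol was compared with control by limma's linear model and moderated test (2-sided) with experiment as a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) of log2 differences come from this model, with 1 residual degree of freedom and a prior of 1.54. The fold description counted probes at least 2-fold different in one direction in both experiments.

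Before the data were examined, 20 miRNA lists with 150 members were fixed from textbook families, clusters and markers, and 147 of the members had a probe. Lists with at least 3 tested members, 18 in all, were tested against the other tested probes by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists. With an estimated correlation the test has only the residual degrees of freedom of the fit, so it could hardly call a list here. The naming rule was fixed at the same time. It takes the 10 probes per direction with the largest change past the threshold, filled up by probes detected on all 4 arrays and of one sign in both experiments with the smallest unadjusted p. It also takes the 10 probes with the highest mean level and up to 4 of the brightest tested members of each list. Further list members and probes at least 2-fold different in both experiments are named here after their values were seen.

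Alternatives fixed beforehand were no background correction, plain subtraction with a floor of 1, cyclic loess, median scaling, no filter, only probes detected on all 4 arrays, the deposited values, no block, a variance trend, a plain per-probe test without moderation and without the block, an estimated list correlation, and leaving out each array in turn. Arrays left out in turn were fitted without the block, so a lone array was assumed to vary like the other group. Alternatives chosen after seeing the data were a correction for guanine and cytosine (GC) content, a stricter filter of 100 above the empty spots, and leaving out probes with a GC content of at least 65%. The GC correction fitted each array's deviation from the probe mean by loess, with a span of 0.75 and degree 2, on target GC content and mean level, and subtracted the fit.

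The model was tested on simulated data of 589 probes in 20 runs, with variances drawn from the fitted prior. In runs with 200 of the 589 probes changed by 2- to 16-fold, it called 74.8% of probes changed 2-fold and 92.5% of probes changed 4-fold. The adjusted threshold depends on the share of changed probes, so these rates need not hold for the data, where 0 probes passed. In runs without any change it called 1 of 11780 probes. Of 100 simulated lists of 10 members shifted by 0.8 on the log2 scale camera called 100, and of as many unshifted lists 6. These list rates need not hold for the data either, where members of a list can move together and log2 ratios followed GC content. Neighbouring miRNA genes were found from a RefSeq gene table, but no position is given because the files name no genome build. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.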

Results

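The arrays measured mature miRNAs in MCF-7 cells kept without ethanol or with 25 mM ethanol for 4 weeks, in 2 experiments with 1 control and 1 ethanol array each (n = 2 arrays per group). Of 1898 human miRNA probes, 518 were detected on control 1, 599 on ethanol 1, 506 on control 2 and 611 on ethanol 2. The mean miRNA brightness was 491, 304, 169 and 210 on these arrays, in the same order. On all 4 arrays 420 probes were detected, and on none 1182.

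The brightest signals included miRNAs abundant in epithelial tumour cells, GC-rich array entries and miR-4454, from the fixed list of entries that resemble fragments of other small RNAs. miR-21-5p, a miRNA raised in many carcinomas, had a mean level of 13.95 (log2) in control and 13.79 in ethanol, a difference of -0.16 ± 0.17 (SE, n = 2). miR-200c-3p, which restrains epithelial-to-mesenchymal transition, had mean levels of 12.86 and 13.07. miR-23a-3p had mean levels of 12.53 and 13.39. The other probes among the 10 with the highest mean level were miR-4497, miR-1273g-3p, miR-3960, miR-4484, miR-3665, miR-4454 and miR-4787-5p, whose log2 differences between ethanol and control ranged from -0.80 (miR-4787-5p) to 0.77 (miR-4454).

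Several markers of other cell types were detected on no array, and others were detected. Of the 8 miRNAs of the pluripotent cell clusters 7 were detected on no array, and of the 7 blood cell markers 5 were detected on none. miR-143-3p and miR-145-5p, typical of smooth muscle and stroma, stayed undetected. miR-122-5p, the liver miRNA, and miR-124-3p, a neuronal miRNA, were also detected on no array. The endothelial miR-126-3p (brightness 135, 274, 174 and 474 on control 1, ethanol 1, control 2 and ethanol 2), miR-214-3p (118, 193, 46.8 and 121), miR-199a-3p and the muscle miRNA miR-206 were detected on all 4 arrays.

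The comparison of ethanol with control asks which miRNAs differed in level after the 4 weeks of exposure. Of the fixed lists 6 were higher in ethanol cells. The miR-30 family rose by a mean of 0.98 (log2, SE over members 0.10), the miR-29 family by 1.16 ± 0.14 and the miR-23/27/24 clusters by 0.96 ± 0.08. The miR-17-92 cluster with its paralogs, the miR-15/16 family and the miR-200 family with miR-205 rose by 0.62, 0.76 and 0.66. The let-7 family fell by 0.62, and a list of GC-rich array signals fell by 0.99. These 8 lists passed limma's camera test with a preset correlation, and none of them passed with an estimated correlation, where the smallest adjusted p was 0.529. With an estimated correlation the test rests on the blocked fit's 1 residual degree of freedom, so it could hardly call any list and decides little. For the GC-rich list the estimate was 0.011, close to the preset 0.01, yet the unadjusted camera p went from 2.95e-09 to 0.105. Most other called lists had estimates above the preset, at 1 for let-7 and miR-30, 0.394 for miR-17-92 and 0.333 for miR-200. It was 0.2 for miR-23/27/24, 0.0476 for miR-15/16 and -0.333 for miR-29. Where members moved together, the p at the preset correlation may be too small. The preset test sets probes against probes and does not measure the spread between the 2 experiments. No single probe passed the limma test across all 589, so single miRNAs below are given as values.

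**Figure D1:**
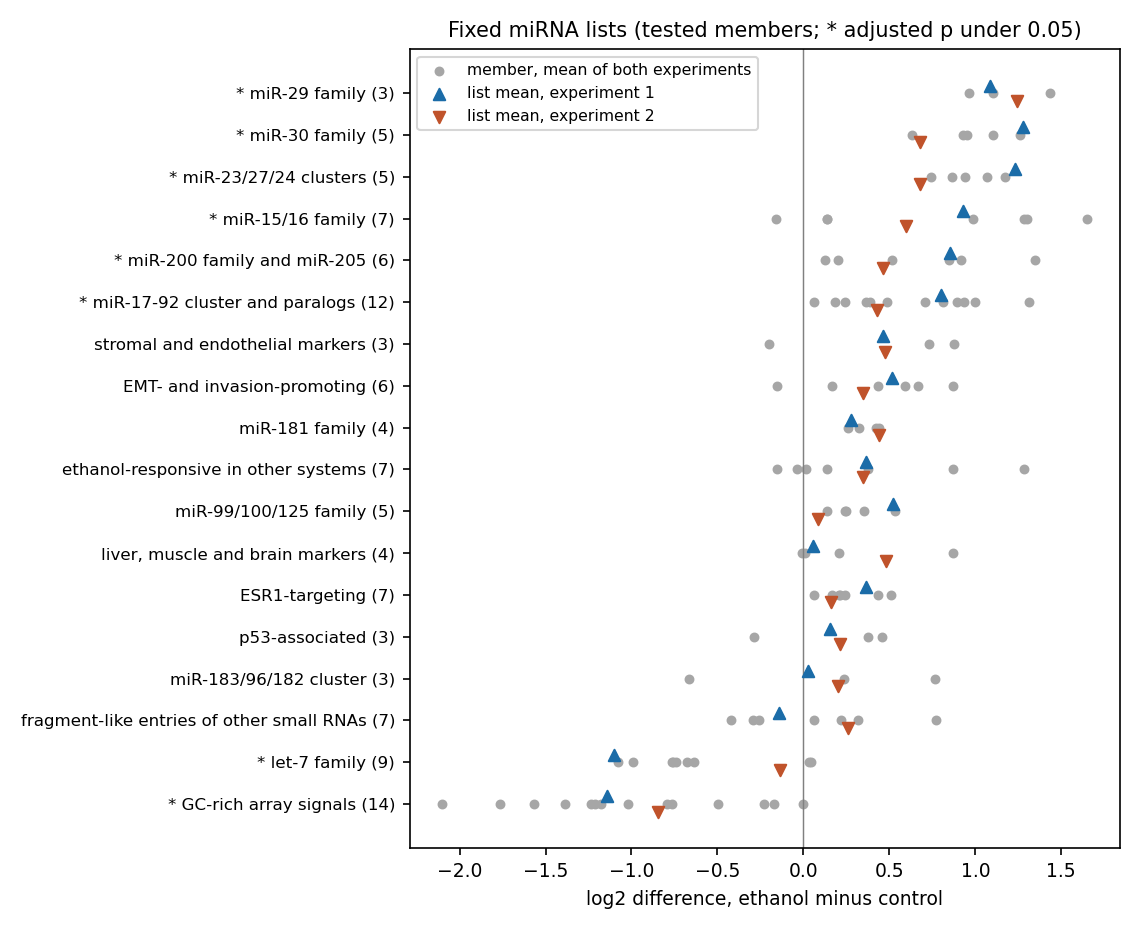
Log2 difference of ethanol minus control for the 18 tested lists, with the number of tested members in brackets. Grey points are members (mean of both experiments), triangles are the list means of experiment 1 (up) and experiment 2 (down), and asterisks mark the 8 lists with a camera adjusted p under 0.05 at a preset correlation. The let-7 mean was -1.10 in experiment 1 and -0.14 in experiment 2.

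All 5 members of the miR-30 family, which is linked to differentiation of epithelial cells, were higher in ethanol in both experiments, with list means of 1.28 and 0.68 (limma camera adjusted p = 0.0033, and adjusted p = 0.529 with an estimated correlation). miR-30e-5p had a log2 difference of 1.26 ± 0.18 and miR-30a-5p of 1.10 ± 0.14. Adjusted over the list alone 2 members passed, against 0 over all probes. The 3 members of the miR-29 family, which targets collagens and other matrix genes, were higher in both experiments, and the family rose by means of 1.08 and 1.24 (limma camera adjusted p = 0.0225, and adjusted p = 0.529 with an estimated correlation). miR-29c-3p stood at 1.43 ± 0.20 and miR-29b-3p at 1.10 ± 0.31, and 1 member passed when adjusted over the list alone.

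The miR-23/27/24 clusters are transcribed from a pair of loci. All 5 members were higher in both experiments, and the list rose by means of 1.23 and 0.68 (limma camera adjusted p = 0.00426, and adjusted p = 0.529 with an estimated correlation). The log2 difference was 1.17 ± 0.14 for miR-27b-3p, 1.07 ± 0.16 for miR-27a-3p and 0.86 ± 0.25 for miR-23a-3p, and 2 members passed when adjusted over the list alone. Members of the higher lists are not all independent, and cross-hybridisation was not tested for these lists. Tested targets differing by at most 2 bases numbered 2 for miR-23a-3p, miR-23b-3p, miR-30a-5p and miR-20b-5p. They numbered 1 for miR-27b-3p, miR-29c-3p and miR-200a-3p, while miR-24-3p, miR-15a-5p and miR-424-5p had none.

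Among the growth-promoting miR-17-92 cluster and its paralogs, 10 of 12 tested members were higher in both experiments. The list rose by means of 0.80 and 0.43 (limma camera adjusted p = 5.84e-04, and adjusted p = 0.529 with an estimated correlation). miR-20b-5p had a log2 difference of 1.31 ± 0.09, miR-106a-5p of 1.00 ± 0.18 and miR-17-5p of 0.90 ± 0.22, whereas miR-92a-3p stood at 0.18 ± 0.09. A group known to restrain the cell cycle moved the same way, as 6 of 7 members of the miR-15/16 family were higher in both experiments and 1, miR-15b-5p, was lower at -0.16 ± 0.12. The family rose by means of 0.93 and 0.60 (limma camera adjusted p = 0.0113, and adjusted p = 0.529 with an estimated correlation). miR-424-5p had a log2 difference of 1.65 ± 0.21, miR-15a-5p of 1.30 ± 0.15 and miR-195-5p of 1.29 ± 0.10. Adjusted over the list alone 1 member of the miR-17-92 list and 3 of the miR-15/16 family passed.

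The miR-200 family and miR-205, which maintain the epithelial state, rose by means of 0.85 and 0.46, with 4 of 6 members higher in both experiments (limma camera adjusted p = 0.0104, and adjusted p = 0.529 with an estimated correlation). miR-200a-3p stood at 1.35 ± 0.10 and miR-141-3p at 0.92 ± 0.29, and miR-205-5p at 0.12 ± 0.13. Adjusted over the list alone 1 member passed. The list of miRNAs that promote epithelial-to-mesenchymal transition and invasion had a mean of 0.43 and missed the threshold (limma camera adjusted p = 0.06). It passed without background correction (adjusted p = 0.0428), without the block (adjusted p = 0.0263), without control 1 (adjusted p = 0.0411) and without ethanol 1 (adjusted p = 0.033). With an estimated correlation the limma camera adjusted p was 0.529 with the block and adjusted p = 0.464 without it. Within it miR-103a-3p stood at 0.67 ± 0.24, miR-9-5p at 0.87 ± 0.14 and miR-222-3p at 0.43 ± 0.14, while miR-10b-5p and miR-155-5p were detected on no array.

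The let-7 family, known for restraint of growth and of RAS and HMGA2, fell with 6 of 9 members lower in both experiments (limma camera adjusted p = 0.0113, and adjusted p = 0.614 with an estimated correlation). let-7e-5p had a log2 difference of -0.99 ± 0.59, let-7d-5p of -0.77 ± 0.20 and let-7a-5p of -0.68 ± 0.13, whereas let-7g-5p stood at 0.03 ± 0.22 and let-7i-5p at 0.04 ± 0.18, and both were lower after the GC correction, at -0.34 and -0.31. The family's mean difference was -1.10 in experiment 1 and -0.14 in experiment 2, and its mean level differed by 1.64 between the experiments. No member passed when adjusted over the list alone.

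**Figure D2:**
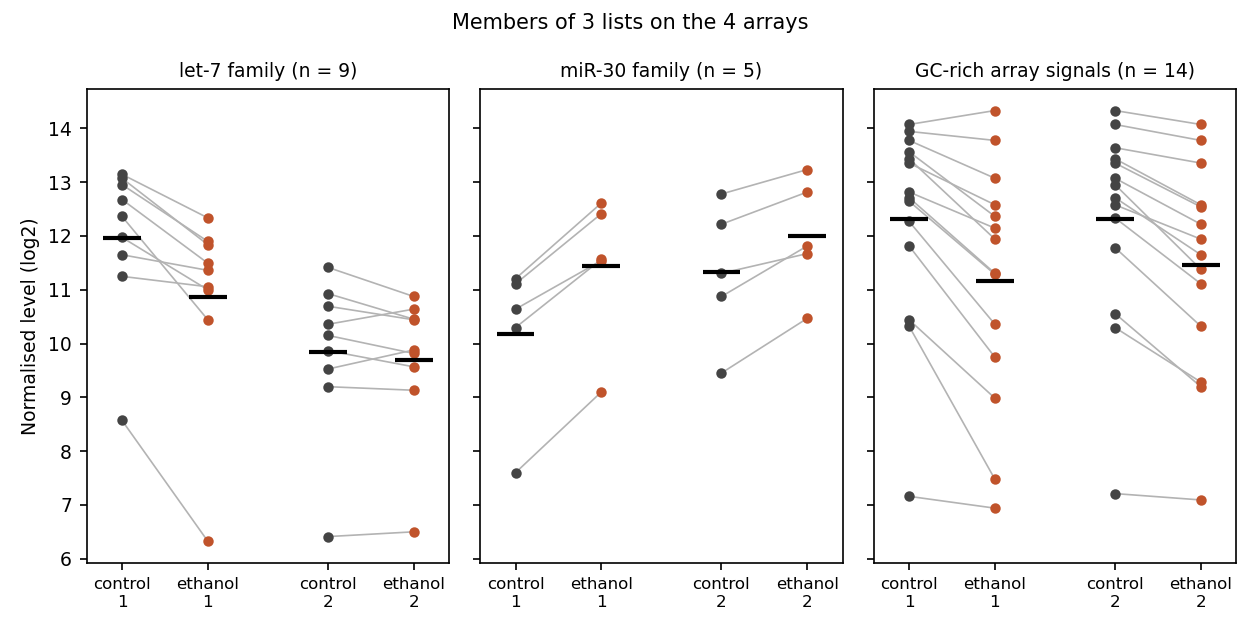
Normalised level (log2) of each member of 3 lists on the 4 arrays, with controls in dark grey and ethanol arrays in orange. Lines join the arrays of one experiment and black bars are means. The let-7 mean was 11.96 on control 1 and 9.84 on control 2, and the miR-30 mean was higher on the ethanol array of both experiments.

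The signals lower in ethanol were mostly GC-rich entries, many of them named from deep sequencing and of unsettled function. In the fixed list of such signals 13 of 14 members were lower in both experiments, and the list fell by 1.14 in experiment 1 and by 0.84 in experiment 2 (limma camera adjusted p = 5.31e-08, and adjusted p = 0.529 with an estimated correlation). miR-2861 had a log2 difference of -2.10 ± 0.47, miR-1915-3p of -1.76 ± 0.21 and miR-663a of -1.39 ± 0.15, while miR-4497, the brightest, stood at 0.00 ± 0.19. Quantile normalization gave miR-4497 the same 2 levels, 14.07 and 14.33, in opposite order in the 2 experiments. Its brightness before normalization fell from 28267 to 20029 in experiment 1 and from 17310 to 12002 in experiment 2. The mean miRNA brightness of the array also fell in experiment 1, from 491 to 304, but rose in experiment 2, from 169 to 210. The fall in experiment 1 therefore cannot be told from a dimmer array. The 0.00 is the mean of opposite log2 ratios, 0.26 in experiment 1 and -0.26 in experiment 2, and does not show an unchanged member. Adjusted over the list alone 9 members passed. Over the 204 probes at least 100 above the empty spots, the log2 ratio of ethanol to control correlated with the target's GC content across probes at a Pearson r of -0.47 in experiment 1 and of -0.60 in experiment 2. Over all 589 tested probes Pearson's r was -0.30 and -0.50, and Spearman's rho was -0.18 and -0.42. For control 2 over control 1 Pearson's r was 0.01 over the 204 probes and -0.01 over all tested ones. Probes are not independent replicates.

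Among single miRNAs, 12 probes were at least 2-fold higher in ethanol in both experiments and 19 at least 2-fold lower, where 1.19 and 1.48 would be expected from independent experiments. The comparison between experiments, control 2 over control 1 with ethanol 2 over ethanol 1, gave 16 higher and 13 lower. After the GC correction 1 higher and 4 lower probes were counted, and with plain background subtraction 58 in all, 31 of them higher. The median GC content was 40.9% for the 12 higher probes and 87.0% for the 19 lower ones, against 55.6% for all tested probes. Besides those above, the probes with the smallest unadjusted p in each direction, whether or not they reached 2-fold, included on the higher side miR-3607-3p at 1.44 ± 0.10, miR-335-5p at 1.28 ± 0.09, miR-148a-3p at 1.25 ± 0.11, miR-203 at 1.06 ± 0.10 and, under 2-fold in both experiments, miR-3170 at 0.84 ± 0.09. On the lower side were miR-654-5p at -2.35 ± 0.22, miR-4467 at -1.94 ± 0.17, miR-3940-5p at -1.56 ± 0.14, miR-4492 at -1.48 ± 0.12, miR-575 at -1.44 ± 0.15, miR-4508 at -1.25 ± 0.09, miR-3196 at -1.21 ± 0.13, miR-1469 at -1.15 ± 0.11 and, under 2-fold in both experiments, miR-4734 at -0.87 ± 0.09. The limma adjusted p of these named probes lay at 0.167 or 0.173.

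**Figure D3:**
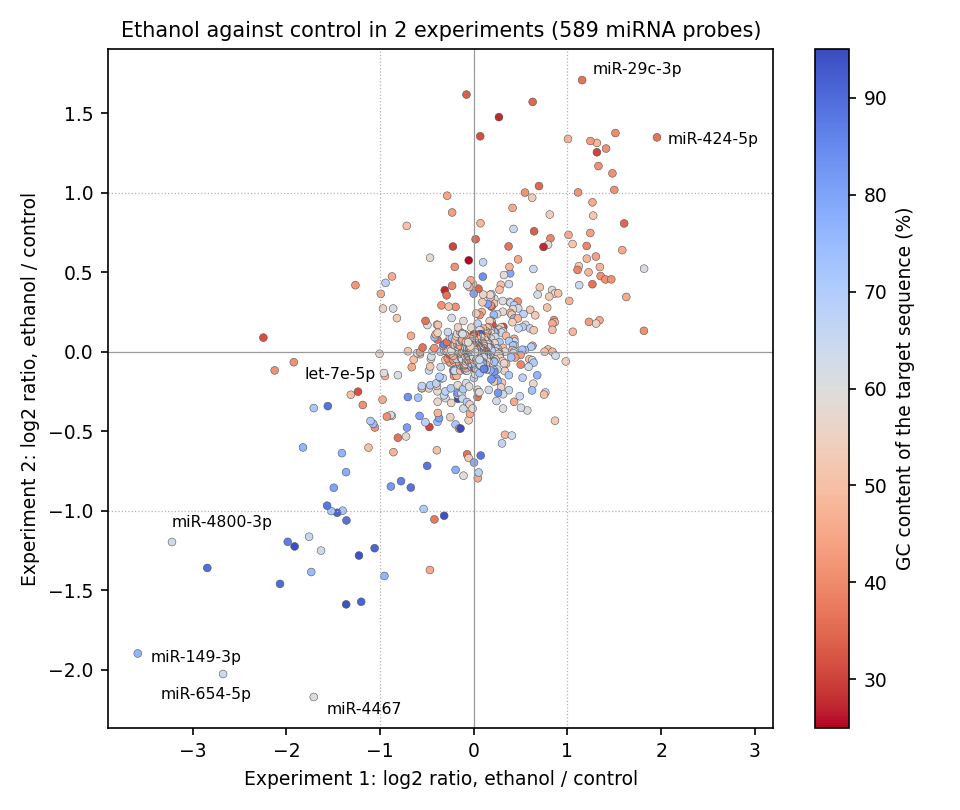
Log2 ratio of ethanol to control in experiment 1 (horizontal) and experiment 2 (vertical) for the 589 tested probes, coloured by the GC content of the target. Dotted lines mark 2-fold. Red points of low GC content fill the upper right and blue points of high GC content the lower left, and Pearson's r across probes was 0.66. For control 2 over control 1 against ethanol 2 over ethanol 1 it was 0.71.

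Of the miRNAs reported to respond to ethanol in other systems, 7 of 12 were tested, and the list had a mean of 0.36 (limma camera adjusted p = 0.137, and adjusted p = 0.0365 without control 1). With an estimated correlation and all arrays the list had an adjusted p = 0.529 with the block and an adjusted p = 0.464 without it. miR-335-5p and miR-9-5p accounted for most of the list's mean, and 2 members passed when adjusted over the list alone. On control 1 miR-9-5p was not detected (brightness 37.5, detection limit 40.1), so the size of its difference rests partly on a level near background. miR-34a-5p stood at 0.38 ± 0.25. The stromal and endothelial list had a mean of 0.47 over 3 tested members (limma camera adjusted p = 0.137). In that list miR-126-3p stood at 0.87 ± 0.13, miR-214-3p at 0.73 ± 0.10 and miR-199a-3p at -0.20 ± 0.17, and 2 members passed when adjusted over the list alone.

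With limma and experiment as a block, 0 of 589 probes had an adjusted p under 0.05 (smallest adjusted p = 0.167), and 94 had an unadjusted p under 0.05, 48 higher and 46 lower, where 29.45 would be expected by chance. The plain per-probe test without moderation and without the block gave 3 past the threshold. The 2 experiments' log2 ratios correlated across probes at a Pearson r of 0.66 and a Spearman rho of 0.51, and 376 of the probes had the same sign in both. For the differences between experiments, control 2 over control 1 against ethanol 2 over ethanol 1, Pearson's r was 0.71. With ethanol 2 over control 1 against ethanol 1 over control 2 it was -0.15. The difference between experiments was thus at least as consistent across probes as that between ethanol and control. The stricter brightness filter gave 53 probes past the limma threshold, median scaling 45 and plain background subtraction 18. With the stricter filter and median scaling the model took a single shared variance for all probes. Median scaling also left median log2 ratios of 0.12 in experiment 1 and -0.32 in experiment 2. After the GC correction the GC-rich list stood at -0.26 ± 0.12, the miR-200 list at 0.37 and the miR-15/16 family at 0.52, all without a call. No call was left without control 1 for let-7 (0.44), miR-17-92 (0.13), miR-29 (0.53), miR-30 (0.40) and miR-200 (0.32), nor without ethanol 2 for these (-0.04, 0.31, 0.45, 0.70 and 0.52) and miR-15/16 (0.74), nor without ethanol 1 for miR-200 (0.80). With 1 array left out, 38 of the 79 probes followed across settings moved by over 1.5 times without changing sign and 16 took both signs. miR-141-3p then ranged from 0.03 to 1.80, miR-200a-3p from 0.76 to 1.93, miR-30e-5p from 0.33 to 2.18, miR-29c-3p from 0.40 to 2.47, miR-195-5p from 0.50 to 2.07 and miR-20b-5p from 0.65 to 1.97. The ranges were 0.18 to 1.61 for miR-17-5p and 0.44 to 1.55 for miR-106a-5p.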

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

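Among the control probes that the comparison did not use, 4 were brighter on every spot of the ethanol array than on every spot of the control array in both experiments. The 5S ribosomal RNA probe hsa-5S-b4 had a log2 ratio of ethanol to control brightness of 0.744 in experiment 1 and 0.473 in experiment 2. The spike-in probes Ctr03-3P, Ctr04-3P and Ctr11-3P had ratios of 0.342, 0.189 and 0.567 in experiment 1 and of 0.543, 0.328 and 0.112 in experiment 2. The 24 control probes were searched only for probes brighter in ethanol, and the 6 probes of 5S ribosomal RNA together had mean ratios of 0.09 and 0.21. Other spike-in probes were dimmer in ethanol in both experiments, among them PUC2PM-20B (-0.71 and -0.27) and a3-PUC2PM-20B (-0.93 and -0.32). Ctr04-3P in experiment 1 (control 43.3, ethanol 49.4) and Ctr11-3P in experiment 2 (48.4 and 52.3) were not far above the detection limits. What the spike-in probes detect is not given in the sources used here.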

How the results depend on the processing

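The stricter filter, the GC correction and leaving out GC-rich probes were chosen after seeing the data. The 6 lists higher in ethanol and the GC-rich list kept their direction under every alternative run. Median scaling moved the median log2 ratio of all tested probes to 0.12 in experiment 1 and -0.32 in experiment 2. The cause of each change below was not tested, except where fewer probes or arrays entered.

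Past the adjusted threshold were 18 probes with plain subtraction, 45 with median scaling, 53 with the stricter filter and 3 with the plain per-probe test. With the stricter filter and median scaling the model took one shared variance for all probes. Unadjusted p under 0.05 came to 157 without a filter, 47 without the block and 33 with the plain test. At least 2-fold in both experiments were 58 probes with subtraction (31 higher) and 5 after the GC correction (1 higher, 4 lower). The correlation of the experiments was 0.43 with subtraction and 0.46 with median scaling.

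List shifts numbered 8 as planned, 10 with cyclic loess and without a filter, 9 without background correction, 7 with subtraction and without GC-rich probes, 6 without the block, 5 with the stricter filter, 5 after the GC correction and 0 with an estimated correlation. Calls were gained by the list promoting mesenchymal transition and invasion without background correction (0.51) and without the block (0.43), and by the ESR1-targeting list and the miR-99 family list with cyclic loess (0.32 and 0.38) and without a filter (0.22 and 0.30). With an array left out calls were gained by the invasion list without control 1 or ethanol 1, the ethanol-responsive list without control 1 (0.47), the miR-99 family list without control 2 (0.52) and the liver, muscle and brain list without ethanol 1 (0.48). The lowest means with an array left out were 0.0853 for the miR-99 family list (without control 1), 0.0582 for the liver, muscle and brain list (without ethanol 2) and 0.14 for the ESR1-targeting list (without control 1). Calls ended for miR-200 at 0.73 (subtraction), 0.77 (stricter filter) and 0.37 (GC correction), for let-7 at -0.56 (stricter filter), for miR-15/16 at 0.52 and the GC-rich list at -0.26 (GC correction). The miR-29 list had too few members for a test under the stricter filter, as miR-29b-3p exceeded that limit on ethanol 2 alone. Without the block calls ended for let-7, miR-200 and miR-29, and with an estimated correlation for let-7 (-0.62), miR-200 (0.66), miR-17-92 (0.62), miR-15/16 (0.76), miR-23/27/24 (0.96), miR-29 (1.16), miR-30 (0.98) and the GC-rich list (-0.99), with the mean unchanged by construction.

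The fragment-like list reversed to -0.24 with subtraction, -0.0525 with cyclic loess, -0.22 with median scaling, -0.0231 with the deposited values and -0.23 without GC-rich probes, and the cluster of miR-183, miR-96 and miR-182 to -0.14 after the GC correction. miR-1273g-3p reversed to -0.14, miR-200c-3p to -0.23 miR-92a-3p to -0.0691, let-7g-5p to -0.19 and let-7i-5p to -0.0373 with median scaling, and let-7g-5p to -0.0326 with cyclic loess. After the GC correction miR-3960 reversed to 0.62, miR-200c-3p to -0.21, miR-92a-3p to -0.0461, let-7g-5p to -0.34 and let-7i-5p to -0.31.

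With an array left out the experiments no longer balance, so their own levels enter. List shifts then ranged from 2 to 9 and unadjusted calls from 23 to 55, with 0 past the threshold each time. List means ranged from -1.68 to 0.44 for let-7, 0.32 to 0.99 for miR-200, 0.13 to 1.10 for miR-17-92, 0.57 to 0.96 for miR-15/16, 0.45 to 1.88 for miR-29, 0.40 to 1.55 for miR-30, -0.14 to 0.25 for the fragment-like list and -0.0948 to 0.32 for the miR-183 cluster. Reversals among probes gave ranges of -1.54 to 0.19 for let-7a-5p, -2.02 to 0.50 for let-7c, -1.78 to 0.25 for let-7d-5p, -1.93 to 0.45 for let-7f-5p, -2.58 to 0.59 for let-7e-5p, -1.03 to 1.09 for let-7g-5p, -0.40 to 0.49 for let-7i-5p, -0.17 to 0.42 for miR-205-5p, -0.10 to 1.52 for miR-106b-5p, -0.64 to 0.32 for miR-15b-5p, -0.0845 to 0.49 for miR-200c-3p, -0.54 to 0.23 for miR-21-5p, -0.56 to 0.24 for miR-4484, -1.87 to 0.14 for miR-4734 and -0.26 to 0.62 for miR-92a-3p. Signal over background limits dim probes: 1182 were detected on no array.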

Other observations

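The other fixed lists did not pass limma's camera test in the planned setting. The family of miR-99, miR-100 and miR-125 had a mean log2 difference of 0.30 (adjusted p = 0.0912), the list of miRNAs that target the oestrogen receptor gene ESR1 0.26 (adjusted p = 0.0712) and the miR-181 family 0.36 (adjusted p = 0.161). The p53-associated list stood at 0.18 (adjusted p = 0.409), the cluster of miR-183, miR-96 and miR-182 at 0.11 (adjusted p = 0.414, -0.14 after the GC correction) and the liver, muscle and brain markers at 0.27 (adjusted p = 0.316). The list of entries that resemble fragments of other small RNAs stood at 0.06 (adjusted p = 0.685) and took the other sign under 5 alternatives with all arrays and without control 2. Calls were gained by the miR-99 family list with cyclic loess (adjusted p = 0.0418), without a filter (adjusted p = 0.0177) and without control 2 (adjusted p = 0.0215). The ESR1-targeting list gained one with cyclic loess (adjusted p = 0.0418) and without a filter (adjusted p = 0.0375), and the liver, muscle and brain markers without ethanol 1 (adjusted p = 0.0325). With an estimated correlation and all arrays the adjusted p of these lists was 0.529 for the miR-99 family, 0.529 for the ESR1-targeting list and 0.71 for the liver, muscle and brain markers.

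The tests chosen only after their results or close relatives of them had been seen were the fragment RNA test, the prediction from probes outside the GC-rich list, the tests of each higher list on its own after the GC correction and the cluster test after the GC correction. The let-7 test for a single deciding array was fixed beforehand, but its reading was changed after its value had been seen.

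The GC-rich signals were lower in ethanol by 0.99 ± 0.17 (log2, SE over 14 members), and 6 other lists were higher. After the GC correction the GC-rich mean was -0.2557 ± 0.124 and its call ended because the mean shrank, and a linear model fitted on the other tested probes predicted -0.9875 for the list, so a trend with GC content and brightness is a candidate explanation that covers its size. The fragment-like list had a mean of 0.05707 with an SE over members of 0.159, so it showed no fall of the GC-rich list's size. Its means were -0.14 in experiment 1 and 0.26 in experiment 2. The list holds entries that resemble fragments of other small RNAs and does not cover fragments of longer transcripts. Whether the ethanol samples held less of that fragment RNA therefore could not be decided. Of the 6 higher lists the correction left 4 with a call at the preset correlation, at 0.3809 ± 0.102 for miR-17-92, 0.5737 ± 0.0768 for miR-23/27/24, 0.8319 ± 0.133 for miR-29 and 0.6444 ± 0.103 for miR-30 (adjusted p = 0.646 for each with an estimated correlation). The rule fixed beforehand for the 6 lists as a set left the question open at 4 lists. The tests of each list on its own, added later, repeat that rule's conditions on the same corrected means. They add only a condition on the SE over members, so they give no separate evidence for these 4. The SE of these means is over members, some of them near-identical, and not over experiments. Whether the GC trend is the whole cause for these 4 lists therefore stays open. For miR-15/16 at 0.5211 ± 0.242 and miR-200 at 0.3676 ± 0.171, from 0.76 ± 0.27 and 0.66 ± 0.19, the calls ended as the means shrank, so trend and ethanol cannot be told apart, and where the trend itself came from was not tested.

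The let-7 family was lower in ethanol by 0.62 ± 0.13. A GC trend is argued against, because after the GC correction the mean was -0.9439 ± 0.126. Cross-hybridisation could not be separated, since 0 members differ from every other member by at least 3 bases. Without control 1 the mean turned to 0.4416. By the rule fixed beforehand, a mean that turned its sign meant that a single array decides the shift. That reading was set aside after the value had been seen, because that fit sets the experiments against each other, whose let-7 levels differ by 1.64. A single deviating array and ethanol therefore cannot be told apart.

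A hypothesis was that the arms of one hairpin would differ from control together, as a change in transcription would produce. Over 82 hairpins with both arms tested the arms' log2 differences correlated across hairpins at 0.09 (one-sided permutation p = 0.208), and at 0.16 after the GC correction (permutation p = 0.07561), so no coupling was detected. An arm needed detection on only 2 arrays, and whether dim arms could show a change was not tested. The arms stood at 1.10 and 0.01 for miR-30a and at 0.07 and 1.17 for miR-27b, but at 0.97 and 1.44 for miR-3607. The result therefore does not decide about transcription. A second hypothesis was that miRNA genes within 10 kb of each other would differ together. Over 54 neighbouring pairs the mean absolute difference was 0.468 against 0.539 when shuffled (one-sided permutation p = 0.04533), and after the GC correction the permutation p was 0.2731, so shared GC content and brightness may explain the likeness.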
